A study of Mus musculus with 10 samples.

How the data were processed

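Small RNA sequencing libraries were compared between 2 groups of lungs from male mice, 10 libraries in all. The labels give all samples the same genotype, a Kras allele with the G12D mutation behind a loxP-flanked stop cassette, and the same time label of 5 months. The 5 lungs of the tumour group had received Adeno-Cre, an adenovirus that carries Cre recombinase, into the trachea at 6 weeks of age, and the 5 lungs of the normal group had not. Total RNA was extracted with TRIzol, and the libraries were made with the NEBNext small RNA kit for Illumina, per the labels' protocols. That kit ligates adapters to RNA ends, a step whose efficiency depends on the RNA's sequence and structure. Levels of different miRNAs within a library are therefore less comparable than levels of one miRNA between libraries. The labels number the lungs within each group and do not say whether each came from its own mouse, so p-values measure the spread between these samples.

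The deposited table holds a normalised signal per mature miRNA and library, not raw counts. Bowtie and DESeq2 are named in the submitters' processing notes, without role or version. The genome build, the miRBase release, the read filters and the rule for reads that match several miRNAs are not given in the sources used here. The authors' values proved to be read counts divided by 1 size factor per library: every one of the 9107 non-zero values was a whole multiple of its library's smallest step, within a tolerance of 0.01 reads (100% whole). The size factors found in this way ranged from 0.504 to 1.38 and equalled DESeq2's median-of-ratios factors up to 1 constant. Read counts could therefore be recovered. The table has 1459 rows, all known mouse miRNAs, of which 12 join the names of miRNAs with the same mature sequence. All 10 sample columns were used.

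Recovered reads per library ranged from 3532762 to 10570480. A value at the level of 3 reads, taken as the floor, corresponds to 2.17 to 5.96 normalised reads depending on the library. Reads without molecular identifiers are not independent molecules, so floors cover counting error only. No 2 libraries agreed within sampling noise. The lowest chi-square per degree of freedom between libraries was 216.6, and all 10 were kept as separate replicates.

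The design fixed before the data were examined assumed raw counts and edgeR, and named limma as the test if the table held normalised values. Because the table held normalised values, the main test was limma (trend, robust) on log2(value + 1), for the 812 miRNAs with a mean of at least 1. Fold changes are on that log2(value + 1) scale, which understates changes of scarce miRNAs. They are tumour minus normal, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median distance from the estimate to either end of its 95% confidence interval for the 288 miRNAs with a mean of at least 100 was 0.638 on the log2 scale, a 1.56-fold change.

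A set of 21 miRNA lists (families, genomic clusters, cell type markers, miRNAs described in lung adenocarcinoma, and markers of other organs) was fixed before the data were examined. The 20 lists with at least 3 tested members were tested with camera, with the correlation between members estimated per list. A joined row was matched to a list through any of its names, an extension of the fixed rule of exact names. Near-identical miRNAs (the let-7 family, the Sfmbt2 cluster, miR-199a with miR-199b, miR-486a with miR-486b) can share reads, and the values of their members are uncertain. For 127 precursors with a mean of at least 10 in both arms, log2((5p + 1)/(3p + 1)) was tested with limma. The share of reads in the 10 most abundant miRNAs was compared with an exact two-sided permutation test over 252 assignments, whose smallest possible p is 0.00794.

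The named miRNAs were set by a rule fixed beforehand. The rule took up to 12 miRNAs in each direction past the threshold (there were none), up to 4 members with the smallest p of each list, 12 miRNAs of prior interest, the 5 most abundant, and precursors with a changed arm ratio (also none). The 8 miRNAs with the smallest p were described as a set after their values were seen. Of these, miR-221-3p, miR-214-3p, miR-122-5p and miR-34a-5p were already named by the rule, and miR-340-3p, miR-181d-5p, miR-151-5p and miR-146b-5p were added, as were miRNAs named for the library that stood apart, for the series' own threshold, for partner arms, for heart muscle, or as further members of the multiciliated list. Chromosomes and host genes are from GENCODE M21 on GRCm38 and coordinates are not given, since the build used for the table is not given in the sources used here. The 5p or 3p side of each annotated hairpin gave a GC content for 779 of the 812 tested miRNAs (95.9%).

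Alternatives were edgeR's quasi-likelihood test with DESeq2 size factors or with TMM, the DESeq2 Wald test and limma-voom, all on recovered reads, and library totals, TMM scaling, removal of the 5 most abundant miRNAs, other filters and pseudocounts, the replicate number as a block, sample quality weights, a GC correction of each library, omission of each library, camera with a preset correlation of 0.01, and fry. The edgeR fit with TMM, TMM scaling, quality weights, GC correction, the pseudocounts for single miRNAs and lists, and the use of recovered reads for arm ratios and for the series' own threshold were chosen after seeing the data. An alternative restricted to known miRNAs was not run, since the table has no predicted ones. The procedure was tested on simulated data for this comparison with 812 miRNAs. With 20 miRNAs changed, limma recovered 7% of those changed 2-fold, 74% of those changed 4-fold and 90% of those changed 8-fold, over 20 runs. With 200 changed, it recovered 36.3%, 88.6% and 97%. Of unchanged miRNAs, 0.104% and 0.598% were called. A list of 13 miRNAs that all moved 2-fold was called in 20 of 20 runs. Simulated miRNAs varied independently, while the estimated correlation within real lists reached 0.88, in the miR-29 family of 3. That result therefore does not give the power for smaller or correlated lists. Of precursors with 1 arm moved 4-fold, 65.2% were called, and 12 calls over the 20 runs fell on unmoved precursors. The arms of a simulated precursor also varied independently, so that share does not give the power for real arm ratios.

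Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.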

Results

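Mature miRNAs were measured by small RNA sequencing in 10 mouse lungs that carried a Kras allele silent until Cre recombinase removes its stop cassette. The normal group held 5 lungs without Adeno-Cre, and the tumour group held 5 lungs after Adeno-Cre in the airways, which switches on oncogenic Kras. The series asks which miRNAs differ between Kras-driven lung tumours and normal lung. The samples were labelled as lung, and the tumour content of each was not given. Recovered reads in the normal libraries were 10570480, 6271382, 3532762, 9186930 and 8005717 for replicates 1 to 5, and those in the tumour libraries were 8428993, 4739766, 7061987, 7685082 and 7977535. Between 791 and 995 miRNAs had reads in a library.

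A few miRNAs made up most reads in both groups. The most abundant was miR-126a-3p, an endothelial miRNA from within Egfl7 on chromosome 2, with 20.92% ± 3.07 of reads (SD, n = 10). Next came miR-143-3p of smooth muscle with 17.64% ± 3.05, miR-26a-5p with 11.17% ± 3.87, miR-21a-5p with 4.79% ± 2.63 and miR-10a-5p with 4.12% ± 1.5. The 10 most abundant miRNAs took 71.42% ± 2.23 of reads in tumour libraries and 71.03% ± 1.79 in normal libraries (SD, n = 5 each). That difference of 0.394 percentage points was smaller than the spread between replicates (exact two-sided permutation p = 0.762). Its sign turned to -0.372 without normal replicate 2 and to -0.275 without tumour replicate 5. None of these 5 miRNAs differed detectably in level between the groups. The log2 fold changes were -0.07 (SE 0.194) for miR-126a-3p, 0.02 (SE 0.234) for miR-143-3p, 0.66 (SE 0.377, limma adjusted p = 0.673) for miR-26a-5p and -0.16 (SE 0.460) for miR-21a-5p. That of miR-10a-5p was -0.04 (SE 0.262), and it was 0.01 under TMM scaling. For miR-26a-5p, normal replicate 2 held 194413 normalised reads, against 631966 to 1105085 in the other normal libraries.

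One normal library stood apart from all others. Normal replicate 2 had a score of 37.2 on the first principal component, which held 34.1% of the variance, while the other 9 libraries lay between -9.28 and 4.43. It held 24155 normalised reads of miR-5099, 27133 of miR-150-5p, a miRNA of mature lymphocytes, and 20903 of miR-375-3p, a miRNA of neuroendocrine cells. In the other libraries miR-150-5p ranged from 3227 to 8472 and miR-375-3p from 3552 to 8581. The other members of the neuroendocrine list went the other way. MiR-7a-5p at 1418 and miR-7b-5p at 10.4 were at their lowest of the 10 libraries in normal replicate 2. The same library had 122 normalised reads of miR-29c-3p and 3240 of miR-34c-5p, both the lowest of the 10. The second component held 14.9% of the variance. On it, tumour replicates 1 to 4 scored -9.47 to -3.82, below the lowest normal score of -3.45. Tumour replicate 5, at 4.33, lay within the range of the normal libraries.

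**Figure D1:**
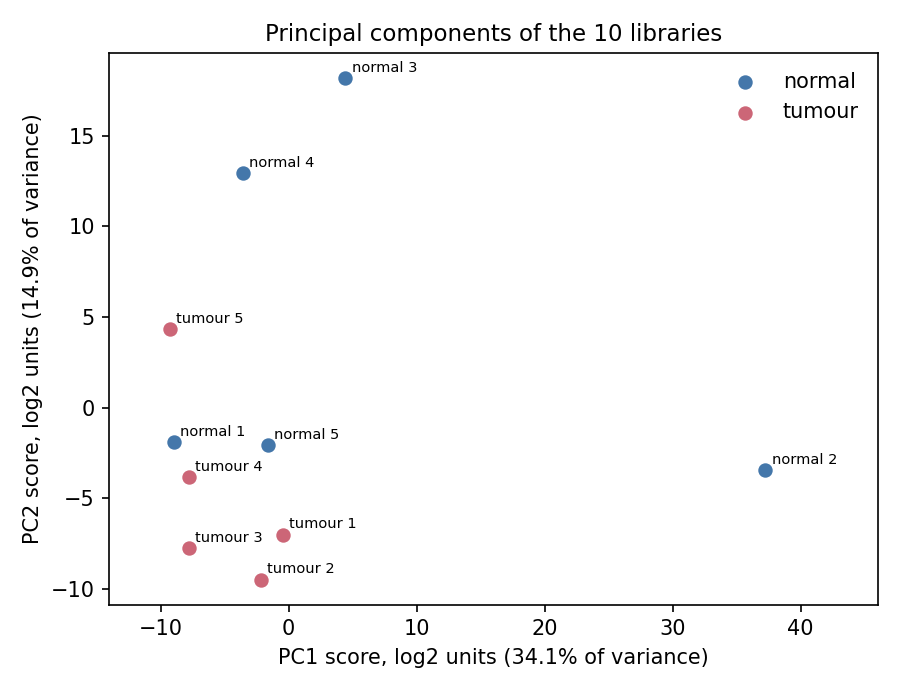
Scores of the 10 libraries on the first and second principal components of log2(value + 1), in log2 units, coloured by group. Normal replicate 2 lies at 37.2 on the first component and every other library at 4.43 or below.

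The 8 miRNAs with the smallest p, a set chosen after their values were seen, included 4 that were higher and 4 that were lower in the tumour group. Mean levels of miR-221-3p, from chromosome X, were 7066 ± 2215 normalised reads in tumour and 2717 ± 447 in normal libraries (SD, n = 5 each), a 2.51-fold difference on the log2(value + 1) scale. The miR-151-5p, from an intron of Ptk2 on chromosome 15, was at 12894 ± 6177 against 4295 ± 881, 2.74-fold on that scale. The fibroblast miRNA miR-214-3p, from an exon of Dnm3os on chromosome 1, was at 5859 ± 2339 against 2363 ± 383, 2.34-fold on that scale. The liver miRNA miR-122-5p, from chromosome 18, was at 2833 ± 1483 against 484 ± 428. Lower in the tumour group were miR-340-3p, from an intron of Rnf130 on chromosome 11, at 387 ± 57.8 against 1422 ± 834, and miR-181d-5p, from an intron of Nanos3 on chromosome 8, at 1107 ± 324 against 3088 ± 1605. The p53 target miR-34a-5p, from chromosome 4, was at 761 ± 214 against 3009 ± 2221, and miR-146b-5p, a regulator of innate immune signalling from an intron of Mfsd13a on chromosome 19, at 50492 ± 10607 against 113050 ± 50538.

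None of the 812 tested miRNAs passed an adjusted p of 0.05 by limma, while 53 had an unadjusted p under 0.05 (28 higher and 25 lower in tumour), where chance alone gives 40.6. Without normal replicate 1 the unadjusted count was 100, and omission of any other library left it between 40 and 66. The lowest limma adjusted p was 0.0727, for miR-340-3p, with a log2 fold change of -1.73 (SE 0.323, 95% CI -2.42 to -1.04). For miR-221-3p it was 0.0772, with 1.33 (SE 0.269, 95% CI 0.76 to 1.90). Adjusted p was 0.110 for miR-181d-5p with -1.41 (SE 0.313), for miR-151-5p with 1.45 (SE 0.338) and for miR-214-3p with 1.23 (SE 0.286). It was 0.195 for miR-34a-5p with -1.70 (SE 0.433), 0.256 for miR-122-5p with 3.07 (SE 0.786) and 0.354 for miR-146b-5p with -1.07 (SE 0.306). The values of the groups did not overlap for 5 of these 8 miRNAs, namely miR-340-3p, miR-221-3p, miR-181d-5p, miR-151-5p and miR-214-3p. Over all tested miRNAs 13 did not overlap (8 higher and 5 lower in tumour), where chance gives 0.794% or 6.44. On recovered reads, edgeR called 2 miRNAs (miR-221-3p higher, miR-340-3p lower), DESeq2 called 7 and limma-voom 0. Without normal replicate 2, or with a mean of at least 50, limma called the same 2, while 1 miRNA was called without normal replicate 1 (miR-34a-5p), without normal replicate 4 (miR-340-3p) or without tumour replicate 1 (miR-221-3p).

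**Figure D2:**
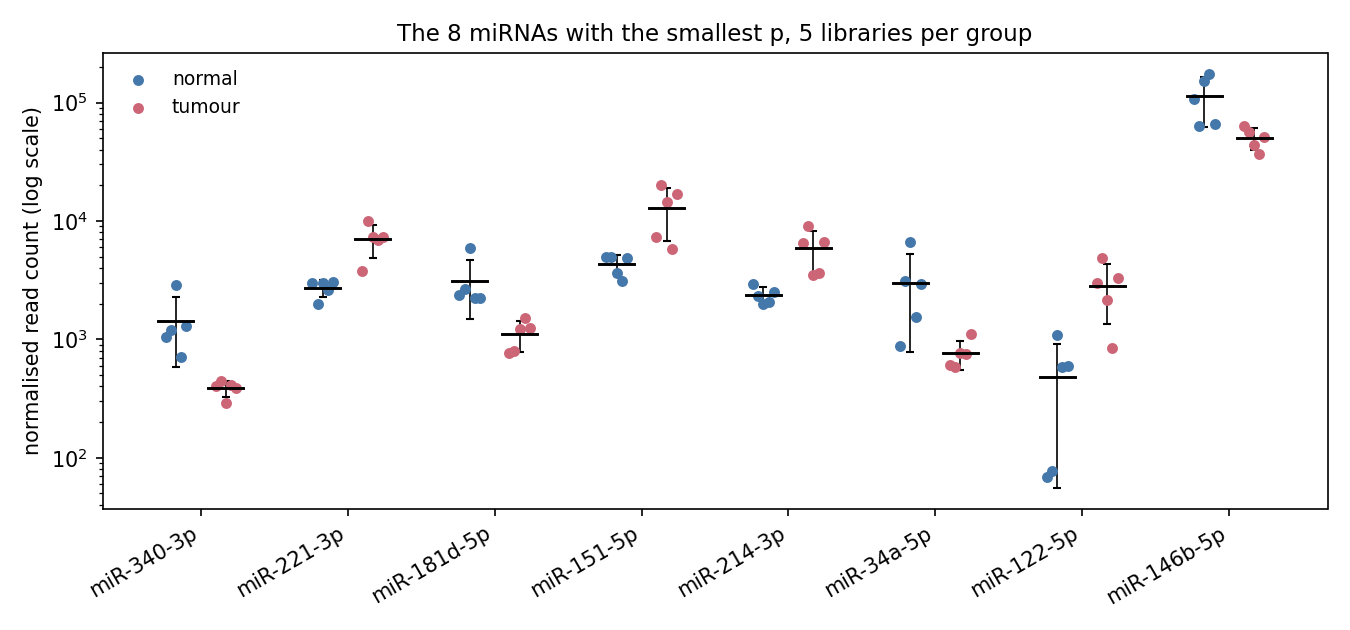
Normalised read counts on a log scale of the 8 miRNAs with the smallest p, for 5 normal and 5 tumour libraries. Points are libraries, horizontal bars are group means and thin bars are SD, and all tumour values of miR-340-3p, 289 to 441.2, lie below the lowest normal value of 710.5.

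The threshold stated by the series, an absolute log2 fold change over 1 with an unadjusted p under 0.05, was met by 37 miRNAs, 16 higher and 21 lower in the tumour group. Of these, 24 had a mean value under 50. All 8 miRNAs above met it, and so did miR-29c-3p (2.53-fold higher on the log2(value + 1) scale), miR-133b-3p (91.9 ± 71.2 normalised reads in tumour and 33.4 ± 45.3 in normal libraries, with normal replicates 2 and 3 at 0.9 and 2, below the floor of 3 reads) and miR-124-3p (0.698 ± 1.13 normalised reads in tumour, below the floor of 3 reads, against 15.0 ± 20.2 in normal libraries). DESeq2 on the recovered reads gave 50 at this threshold, 10 higher and 40 lower.

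MiRNAs often described as raised in lung adenocarcinoma did not shift together. Of 12 tested members, 6 were higher and 6 lower in the tumour group, with a median log2 fold change of 0.03 and a mean of -0.002 (camera adjusted p = 0.553 with an estimated correlation). The oncogenic miR-21a-5p was at 290990 ± 90386 normalised reads in tumour and 401340 ± 294740 in normal libraries. Log2 fold changes were 0.07 (SE 0.383) for miR-31-5p and 0.51 (SE 0.439) for miR-31-3p, -0.17 (SE 0.438) for the immune miRNA miR-155-5p, and 0.26 (SE 0.286) for the hypoxia-induced miR-210-3p. Those of miR-130b-3p and miR-135b-5p were -0.67 (SE 0.466) and -1.33 (SE 1.01), with 1 normal library of miR-130b-3p at 328.4 (replicate 2) and normal replicates 3 and 4 of miR-135b-5p at 710.7 and 1267. Normal replicate 2 also held 9.5 normalised reads of miR-31-3p, against 38.8 to 69.5 in the other normal libraries. It held 3314 of miR-155-5p, against 384.9 to 1367. When 1 library was left out, the median ran from -0.06 without tumour replicate 4 to 0.18 without tumour replicate 5. Only miR-221-3p of this list had a p under 0.05, and it was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.00228), against 0 over all miRNAs.

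MiRNAs described as lowered in lung adenocarcinoma were likewise split, 8 higher and 7 lower of 15, with a median of 0.02 (adjusted p = 0.945 with an estimated correlation). The mean was -0.16, opposite in sign to the median and to the direction of the list test. The smallest p values of this list belonged to the joined row of miR-486a-5p and miR-486b-5p (log2 fold change -1.34, SE 0.559), to miR-338-3p (0.71, SE 0.32) and to miR-451a (-1.19, SE 0.561), each with a limma adjusted p of 0.673, while miR-497a-5p and miR-126a-5p had log2 fold changes of 0.34 and 0.32. Let-7 miRNAs, which repress Ras and Hmga2, had 8 of 9 members with a value above 0, but a median of 0.16 (adjusted p = 0.499 with an estimated correlation), or 0.03 without normal replicate 2 and 0.26 without normal replicate 1. In that family the log2 fold changes were 0.21 (SE 0.226) for let-7a-5p, 0.39 (SE 0.383) for let-7f-5p, 0.18 (SE 0.197) for let-7d-5p and 0.61 (SE 0.421) for miR-98-5p. The miR-17/miR-92a clusters, linked to Myc and the cell cycle, had 10 of 13 members below 0, with a median of -0.10 (adjusted p = 0.777 with an estimated correlation). Their smallest p values belonged to miR-106a-5p (-0.50, SE 0.316), miR-18a-5p (-0.41, SE 0.276), miR-93-5p (-0.30, SE 0.212) and miR-25-3p (-0.40, SE 0.327). In the miR-15/miR-16 family, which represses cell cycle genes, 4 of 5 lay above 0 with a median of 0.34 (adjusted p = 0.499 with an estimated correlation), with miR-16-5p at 0.45, miR-15a-5p at 0.47 and miR-195a-5p at 0.06. Without normal replicate 2 the median of that family was 0.09. When 1 library was left out, the median of the lowered list ran from -0.04 (without tumour replicate 4) to 0.08 (without normal replicate 5), and that of the miR-17/miR-92a clusters from -0.20 (without tumour replicate 3) to -0.04 (without tumour replicate 2).

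**Figure D3:**
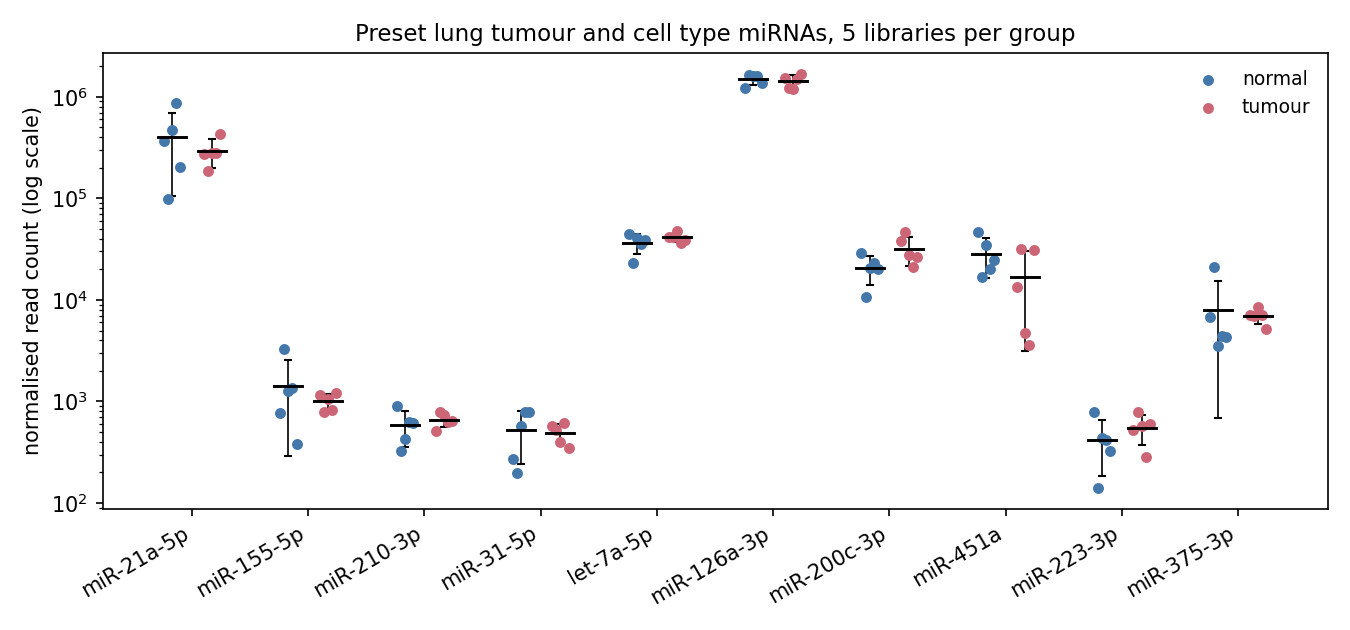
Normalised read counts on a log scale of 10 miRNAs fixed before the data were examined, for 5 normal and 5 tumour libraries. Points are libraries, horizontal bars are group means and thin bars are SD, and the groups overlap for each of the 10, including miR-21a-5p.

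All 5 members of the miR-200 family, which maintains epithelial identity, lay above 0, with a median of 0.50. The list had an adjusted p of 0.0292 with the preset correlation and an adjusted p of 0.499 with an estimated correlation. Mean miR-200c-3p was 31850 ± 10178 in tumour and 20689 ± 6578 in normal libraries (log2 fold change 0.64, SE 0.296, limma adjusted p = 0.673), and those of miR-200a-3p, miR-200b-3p and miR-141-3p were 0.68, 0.37 and 0.50. All 5 members of the miR-30 family lay above 0 with a median of 0.21 (adjusted p = 0.0405 with the preset correlation, adjusted p = 0.403 with an estimated correlation). MiR-30b-5p was 2.09-fold higher on the log2(value + 1) scale with no overlap between groups and was the 1 member past the threshold when adjusted over the list alone, against 0 over all miRNAs. Values for miR-30c-5p, miR-30a-5p and miR-30e-5p were 0.51, 0.20 and 0.21. Of 6 miRNAs of multiciliated airway cells, 4 lay above 0 with a median of 0.48 (adjusted p = 0.403 with an estimated correlation), among them miR-34b-5p at 0.98 (SE 0.604), miR-34b-3p at 0.52, miR-34c-5p at 0.74 and miR-34c-3p at 0.43, while miR-449a-5p was at -0.11 and miR-449c-5p at -0.05. The miR-183 cluster had 1 of 3 above 0 and a median of -0.15 (adjusted p = 0.945 with an estimated correlation), with miR-183-5p at -0.27, miR-182-5p at -0.15 and miR-96-5p at 0.38. The value of miR-96-5p rested on normal replicate 2, at 114 normalised reads against 977 to 1496 in the other normal libraries. The squamous and basal cell miRNA miR-205-5p was at 239 ± 271 against 92.7 ± 87.4. Tumour replicate 3 held 711.5 of it and the other tumour libraries 36.5 to 205.5, with normal replicate 5 at 245.1. The neuroendocrine list (miR-375-3p 0.14, miR-7a-5p -0.09, miR-7b-5p -0.14) had a median of -0.09 (adjusted p = 0.945 with an estimated correlation). After a GC correction, which drops miRNAs without a GC content, the median was 0.07 and may rest on fewer members. The list test of the neuroendocrine list pointed up, against the sign of its median. Without normal replicate 2, the median of the miR-200 family was 0.17 and that of the miR-30 family 0.02, which was 0.44 without normal replicate 4. The median of the miR-183 cluster ran from -0.29 (without normal replicate 1) to -0.02 (without tumour replicate 4), and that of the neuroendocrine list from -0.35 (without normal replicate 2) to 0.17 (without normal replicate 1).

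All 5 fibroblast rows lay above 0, with a median of 0.69. The list had an adjusted p of 0.00301 with the preset correlation and an adjusted p of 0.403 with an estimated correlation. Of its members, miR-214-3p passed when adjusted over the list alone (1 of 5, against 0 over all miRNAs). The joined row of miR-199a-3p and miR-199b-3p was at 0.77 (SE 0.429), miR-199b-5p at 0.69 (SE 0.375) and miR-214-5p at 0.44 (SE 0.256). The miR-29 family, which represses collagen genes, had 3 of 3 members above 0 and a median of 1.00 (adjusted p = 0.00301 with the preset correlation, adjusted p = 0.403 with an estimated correlation). MiR-29a-3p was at 38653 ± 4351 normalised reads in tumour and 22513 ± 8646 in normal libraries, without overlap (log2 fold change 0.86, SE 0.266, limma adjusted p = 0.472). MiR-29c-3p was at 1.34 (SE 0.532) and miR-29b-3p at 1.00 (SE 0.524), and 2 of these 3 passed when adjusted over the list alone. Without normal replicate 2, the medians were 0.29 for the fibroblast list and 0.68 for the miR-29 family. Smooth muscle miRNAs had 4 of 4 above 0 with a median of 0.21 (adjusted p = 0.499 with an estimated correlation), with miR-145a-5p at 0.23, miR-145a-3p at 0.20 and miR-143-5p at 0.27, and the median was -0.03 without normal replicate 2. The endothelial pair of miR-126a-3p and miR-126a-5p had 1 member above and 1 below 0, with a median of 0.12 (0.03 without normal replicate 2, 0.04 without tumour replicate 5 and 0.21 without tumour replicate 2), and was too small for a list test.

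Red blood cell miRNAs had negative values in all 4 rows, with a median of -1.15, or -0.81 without tumour replicate 3 and -0.87 without tumour replicate 4. Those 2 libraries held the lowest miR-451a levels, 4699 and 3628 normalised reads, while the other 3 tumour libraries held 13257, 31794 and 30673 against 16949 to 46201 in the normal group. The list had an adjusted p of 0.0179 with the preset correlation and an adjusted p of 0.403 with an estimated correlation. MiR-451a was at 16810 ± 13691 in tumour and 28541 ± 11930 in normal libraries (log2 fold change -1.19, SE 0.561, limma adjusted p = 0.673). The joined row of miR-486a-5p and miR-486b-5p was at -1.34 (SE 0.559), miR-144-5p at -1.07 and miR-144-3p at -1.11. Lymphocyte miRNAs lay below 0 in 6 of 6 rows, with a median of -0.28 that was -0.01 without normal replicate 2 (adjusted p = 0.738 with an estimated correlation), with miR-342-5p at -0.57, miR-342-3p at -0.29, miR-181a-5p at -0.28 and miR-181b-5p at -0.32. Myeloid miRNAs went both ways (3 above 0, 4 below, adjusted p = 0.945 with an estimated correlation), with miR-223-3p at 0.53, miR-223-5p at -0.48 and miR-511-3p at 0.70. Normal replicate 2 held 140.5 normalised reads of miR-223-3p, against 327.4 to 783.6 in the other normal libraries. It held 4.7 of miR-511-3p, against 23.8 to 35.4. Mean miR-511-5p was 2.81 normalised reads in tumour and 1.63 in normal libraries, within the range of the floor of 3 reads or below it. The list's median was -0.17 and its mean 0.07, the latter with the sign of the list test. After a GC correction, which drops miRNAs without a GC content, the median was 0.60. It may rest on fewer members, so the change cannot be put down to GC content. The median was -0.06 without normal replicate 4. That of the lymphocyte list was -0.50 without normal replicate 1.

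Heart and skeletal muscle miRNAs varied widely between lungs. Of 7 members, 6 lay above 0 with a median of 1.496 (adjusted p = 0.0179 with the preset correlation, adjusted p = 0.403 with an estimated correlation). The median was 0.68 without normal replicate 3, 0.71 without tumour replicate 3 and 2.27 without normal replicate 1. MiR-133a-3p ranged from 81.4 to 3314 normalised reads in normal and from 469 to 3817 in tumour libraries (log2 fold change 2.12, SE 0.982), while miR-133b-3p was at 2.58 (SE 1.08; 3.37 without normal replicate 1 and 1.93 without normal replicate 2) and miR-208a-3p at 1.496 (SE 0.97). MiR-206-3p, of skeletal muscle, had 10158 normalised reads in tumour replicate 3 and 27 or fewer in the other 9 libraries. Among markers of other organs, 1 of 5 lay above 0, with a median of -0.49 (adjusted p = 0.939 with an estimated correlation). That median ran from -0.75 (without tumour replicate 3) to -0.21 (without normal replicate 1) when 1 library was left out. MiR-122-5p was the 1 that passed when adjusted over the list alone, against 0 over all miRNAs, and the log2 fold changes of miR-124-3p, miR-217-5p and miR-9-5p were -2.04, -0.78 and -0.49. That of miR-124-3p rested on normal replicates 1 and 2, at 26 and 45.6 normalised reads against 0 to 2.6 in the other 8 libraries, and was -1.50 without the former and -1.30 without the latter.

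In the imprinted Dlk1-Dio3 cluster, 32 of 47 tested miRNAs lay below 0 (median -0.11, adjusted p = 0.866 with an estimated correlation), with miR-376c-3p at -0.87 (SE 0.426) and miR-485-5p at -0.84 (SE 0.476), while miR-667-3p at -0.98 was near the floor of 3 reads and miR-376a-3p had means of 2.41 and 0.696 normalised reads in tumour and normal libraries, within that floor's range or below it. In the Sfmbt2 cluster, whose members share reads, 31 of 48 lay below 0 (median -0.19, adjusted p = 0.945 with an estimated correlation). Its joined row of miR-669a-5p and miR-669p-5p was at -0.68 (SE 0.313), miR-467a-5p and miR-467b-5p had identical values at -0.48 (SE 0.224), and miR-466i-3p, near the floor, was at 0.92. Both medians turned positive when 1 library was left out: 0.06 for Dlk1-Dio3 without normal replicate 5, against -0.27 without normal replicate 3, and 0.03 for Sfmbt2 without normal replicate 1, against -0.41 without normal replicate 2. In all, 0 of 20 lists passed with an estimated correlation, 6 with the preset correlation and 0 by fry. Estimated correlations of those 6 lists ran from 0.257 (miR-30 family) to 0.88 (miR-29 family), far above the preset 0.01. Their adjusted p values with the preset correlation are therefore too low. Adjusted over the list alone, 5 lists held a miRNA past the threshold and 16 held none.

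**Figure D4:**
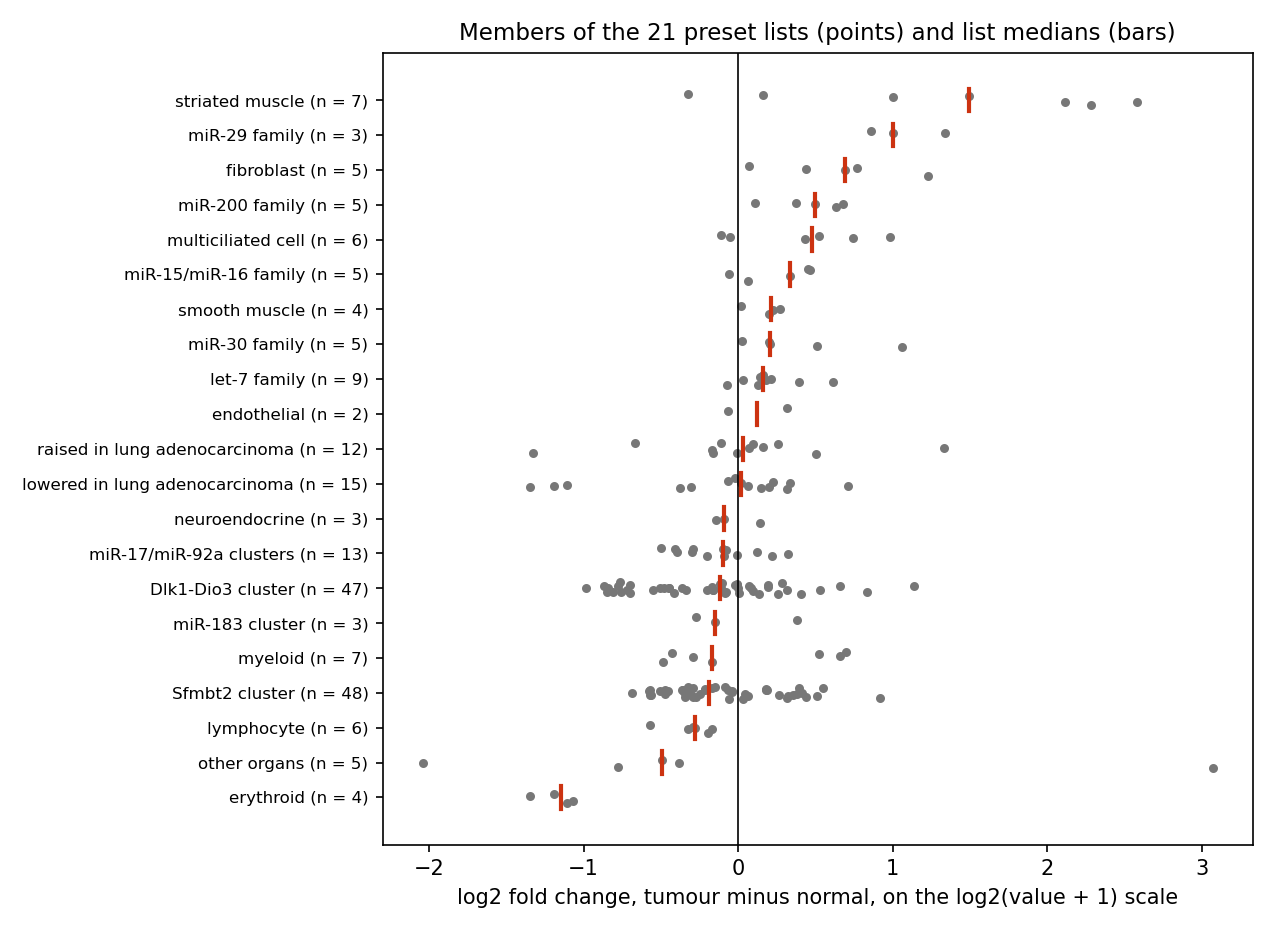
Log2 fold changes, tumour minus normal on the log2(value + 1) scale, of the tested members of the 21 preset lists (points) with list medians (bars). Medians run from -1.15 for the erythroid list to 1.496 for striated muscle, and the spread of members crosses 0 for most lists.

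For 4 of the 8 miRNAs with the smallest p, the log2 fold change of the partner arm was smaller in size and had a limma p above 0.05. For miR-221 the 3p arm was at 1.33 and the 5p arm at -0.18 (SE 0.258), so that the log2 ratio of 5p to 3p was -4.55 ± 0.634 in tumour and -3.04 ± 0.314 in normal libraries (SD, n = 5 each). For miR-151 the 5p arm was at 1.45 and the 3p arm at -0.40 (SE 0.335), for miR-340 the 3p arm at -1.73 and the 5p arm at -0.27 (SE 0.396), and for miR-214 the 3p arm at 1.23 and the 5p arm at 0.44 (SE 0.256). The arms of miR-146b and miR-122 had values of the same sign, with miR-146b-3p at -0.998 (SE 0.351, limma adjusted p = 0.644) and miR-122-3p at 1.60 (SE 0.576, adjusted p = 0.673) with a mean of 1.96 normalised reads in normal libraries, near or below the floor of 3 reads. MiR-34a-3p, also near the floor, was at 1.67 (SE 0.545, limma adjusted p = 0.515), opposite in sign to its 5p arm. None of the 127 arm ratios passed an adjusted p of 0.05 by limma, and 12 had an unadjusted p under 0.05. That count was 21 without normal replicate 1, 7 without normal replicate 3 and 6 without tumour replicate 3. The lowest adjusted p values were 0.0741 for miR-221, with a difference of -1.51 (SE 0.328, 95% CI -2.22 to -0.79), and 0.135 for miR-151, with 1.86 (SE 0.48). Without tumour replicate 1, 1 ratio was called, that of miR-221.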

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

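In this part the tests of depth, of the whole locus, of batch and of muscle were chosen only after the result was seen. The pattern of arms was found from the same miRNAs that it was tested on, and the 4 precursors were settled after their arm values were known.

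Of 182 group tests, 15 had 1 library far from the rest of its group (gap over range above 0.71), where chance gives about 5% of them. For miRNAs the gap over range was taken on log2(value + 1), while the values given here are normalised reads. Of the 15, 6 were in normal replicate 2. There, normalised reads were 32265 for let-7f-5p (others 111331 to 184590), 114 for miR-96-5p (977 to 1496), 205 for miR-214-5p (363.3 to 436.3), 45 for miR-144-5p (178 to 301) and 4.7 for miR-511-3p (23.8 to 35.4), and the share of the 10 most abundant miRNAs was 68.0% (71.3 to 72.6). In tumour replicate 4, miR-183-5p was at 2183 (3141 to 3315), miR-182-5p from the same cluster at 4719 (7143 to 8245) and miR-181b-5p at 6705 (3690 to 4355). In tumour replicate 5, miR-34c-3p was at 944 (1853 to 2087) and miR-133a-3p at 469 (2291 to 3817). In tumour replicate 2, miR-135b-5p was at 15 (81 to 151) and miR-29a-3p at 46418 (36396 to 37176). In tumour replicate 3, miR-206-3p was at 10158 (12 to 27), and in normal replicate 3, miR-181d-5p was at 5944 (2233 to 2649).

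Normal replicate 2 deviated from the median of the other libraries by a root mean square of 1.47 on the log2 scale over 325 miRNAs, where the highest other library had 0.753. Lower depth does not account for it, since the highest deviation among libraries with fewer reads, normal replicate 3 and tumour replicate 2, was 0.75. The hairpin side's GC content as the whole cause is argued against as well. After each library's trend with it was removed, the deviation was 1.41, still 1.87 times the highest of the other 9. The GC content of the mature miRNAs themselves was not tested. A partial GC trend stays open, with a rho of 0.27 between deviation and GC across miRNAs, against -0.27 to 0.22 elsewhere. More leukocytes in that piece of lung may contribute, as the lymphocyte list stood 1.61 above the other libraries after GC correction. MiR-142a-5p was also high there, at 24990, but miR-142a-3p was at 1577, inside the range of the others. The myeloid miRNAs miR-223-3p and miR-511-3p, at 140.5 and 4.7 normalised reads, were at their lowest of the 10 libraries. MiR-223-5p, at 631.2, lay inside the range of the others. Leukocytes therefore cannot be told apart from a technical change of the library, and no other biological explanation was tested.

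MiR-340-3p, miR-221-3p, miR-151-5p and miR-214-3p stood apart between the groups without their partner arm. A trend with the GC content of the hairpin side is argued against, as the 8 miRNAs with the smallest p kept a median share of 1.02 of their log2 fold change after GC correction. The GC content of the mature miRNAs themselves was not tested, so a trend with it stays open. A changed output of the whole locus would move both arms alike and leave the arm ratio unchanged. Of the 4 precursors, 0 had an arm ratio past the adjusted threshold. Their unadjusted limma p values were 0.000583 for miR-221, 0.00213 for miR-151, 0.0238 for miR-340 and 0.0424 for miR-214. These arms were picked because 1 of them was extreme, so the ratios cannot decide and this stays open. A difference in ligation or library batch between the groups also stays open, since the labels give 0 libraries with a batch. Regulation of single mature miRNAs by oncogenic Kras was not tested apart from these.

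Striated muscle miRNAs varied widely between libraries. Heart muscle in the dissected tissue is a candidate source: miR-208a-3p, encoded in an intron of the heart myosin gene Myh6, followed miR-133a-3p across the 10 libraries (Spearman's rho 0.915, permutation p = 0.00059, adjusted 0.000885; Pearson's r 0.888, permutation p = 9e-05, adjusted 0.00027; 3 relations tested). Pearson's r was 0.814 without normal replicates 2 and 3, while miR-208b-3p did not follow (r 0.036, rho -0.212, and r -0.783 without the same 2 libraries). Skeletal muscle in tumour replicate 3 may add to it, with 10158 normalised reads of miR-206-3p against 27 or fewer in the other libraries. There miR-133b-3p, from the same transcript as miR-206-3p, was 1.91 times as high as in the next library, a far smaller rise. MiR-133a-3p was also highest there, at 3817, so miR-133b-3p cannot tell skeletal from heart muscle. An effect of the Adeno-Cre group itself stays open, with an adjusted p of 0.403 for the list.

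The 10 samples were also split in 100 ways, the real one included. At an unadjusted p under 0.05, 18 of the 100 splits gave as many miRNAs by limma as the real 53, so that chance cannot be excluded for that count. The highest other count was 120, with normal replicates 1 and 4 and tumour replicates 3, 4 and 5 on one side. On that side miR-34c-5p, a miRNA picked after the split was seen, was at 25596 to 37736 normalised reads. In the remaining libraries of both groups it was at 3240 to 14773. No other structure of the samples was tested. For the 2 miRNAs called by edgeR on the recovered reads, 2 of 100 splits gave as many, the real one included. The other split gave 4, with normal replicates 1, 3, 4 and 5 and tumour replicate 5 on one side. The share lay below 0.05, without adjustment for the other counts tested here. Since limma called 0, chance is not excluded for the edgeR count. The real counts of 0 miRNAs by limma, 0 lists and 0 arm ratios are met by any split (100 of 100), so that these say nothing on chance. The highest other counts were 5 miRNAs, 0 lists and 4 arm ratios.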

How the results depend on the processing

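The edgeR fit with TMM, the quality weights, the GC correction, the TMM scaling, the pseudocounts for single miRNAs and lists, the DESeq2 run at the series' threshold and the arm ratios on recovered reads were tests chosen only after the data were seen. Against 0 changed miRNAs in the main test, edgeR on the recovered reads called 2 with DESeq2 size factors and 2 with TMM, a mean of at least 50 gave 2 (fewer miRNAs tested), no filter 4, quality weights 3 (weight 0.194 for normal replicate 2) and DESeq2 7. The series' own threshold gave 37, and 50 with DESeq2. The count was 0 with limma-voom, library totals, TMM scaling, GC correction, pseudocounts of 0.1 and 5, and without the 5 most abundant. Leaving out 1 library gave 0 to 2 miRNAs (2 without normal replicate 2, 1 each without normal replicate 1, normal replicate 4 or tumour replicate 1), 0 lists, and 0 to 1 arm ratios (1 without tumour replicate 1). The preset correlation gave 6 lists instead of 0. No named miRNA or list reversed its direction where an alternative called it. With 0 calls in the main test, other changes of sign were not counted as reversals. Of the values of named miRNAs, 2007 held their place, 41 moved by more than their error and 25 passed the threshold. Of list values, 406 held, 92 moved and 6 passed. The difference in the share of the 10 most abundant was 0.394 percentage points, reversed to -0.365 with the 10 most abundant within each sample, and -0.372 (without normal replicate 2) to 0.971 when 1 library was left out, also negative at -0.275 without tumour replicate 5. The cause of these changes was not tested. With the replicate number as a block the counts were 0 miRNAs, 0 lists and 0 arm ratios, and the paired share test gave an exact p of 0.75, where the smallest possible is 0.0625. Pairing was checked on deviations from each group's mean, over 337 miRNAs with a mean of at least 50. These deviations correlated between -0.32 and 0.26 for same-numbered samples. Of 10 samples, 2 correlated best with their own number, so the numbers were not treated as pairs. The alternative of known miRNAs only was not run, as no predicted ones are in the table. Spread between lungs, more than depth, limits abundant miRNAs; at 3532762 reads (normal replicate 3) a value under 5.96 is below 3 reads.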

Other observations

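MiR-122-5p, the main miRNA of hepatocytes, was present in all 10 lungs at levels that differed widely within a group. The 5 normal libraries held 68.6, 77.8, 1096, 587 and 591 normalised reads and the 5 tumour libraries held 2986, 4873, 2155, 849.7 and 3304. The values of normal replicate 3 and tumour replicate 4 overlapped across groups, and the limma adjusted p was 0.256. Of the markers of other organs, miR-217-5p was at 3.42 ± 3.16 in tumour and 6.41 ± 5.26 in normal libraries, and the brain miRNA miR-9-5p was at 340 ± 173 and 564 ± 430 (SD, n = 5 each).

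Within the normal group, miR-21a-5p spanned from 98659 normalised reads in replicate 2 to 860308 in replicate 4, a range that contains every tumour library (184021 to 435015). MiR-34a-5p was highest in normal replicate 3 at 6621 and lowest among normal libraries in replicate 1 at 874, below the 1115 of tumour replicate 5. MiR-130b-5p was at 695 in normal replicate 2 and between 8.1 and 41.7 in the other 9 libraries.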
